A study of Drosophila melanogaster with 4 samples.

How the data were processed

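RNA from heads of unmated Oregon-R wild-type Drosophila melanogaster males was compared on two-colour cDNA arrays, after 7 days on food with 1.5 mg/ml pilocarpine or on normal food. Per the labels, 8 pools of frozen heads were used, and each of the 4 arrays carried the treated and the untreated pool of one parallel set of vials, so that the 4 arrays are 4 biological replicates. The treated RNA was labelled with Cy5 on replicates 1 and 2 and with Cy3 on replicates 3 and 4. Every array is a comparison of treated with untreated RNA, and the mean log2 ratio over the arrays was tested against 0.

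Per the labels and the series' design text, slides were scanned with a GenePix scanner, spots were quantified in GenePix Pro 6.0, and ratios were normalized in Acuity 4.0 without spots of low raw intensity. The authors then filtered spots on saturated pixels, flags, uniformity and signal over background, and took spots analysable on at least 3 of the 4 arrays on to SAM 3.0, per the labels. The deposited values are log2 ratios of the 2 channels, with an empty cell where a spot was left out. Scanner intensities were not used here, so background correction and normalization stand as the authors left them. The log base was read from the values: the highest one, 16.61, recurs exactly in 11 cells and is the log2 of a ratio of 100000, a ceiling. Those 11 cells were left out. The column medians were -0.14, -0.48, -0.29 and -0.42 for replicates 1 to 4, so the deposited ratios are not centred on 0.

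The labels give the dye of each channel but not which channel is the numerator. Under a rule fixed in advance, the deposited ratio was read as Cy5 over Cy3 and replicates 3 and 4 were turned in sign, unless all 4 correlations between arrays of opposite dye orientation exceeded 0.1 as deposited. They were 0.05, 0.14, -0.08 and 0.09, so the sign was turned. This outcome cannot decide the direction, because pairs of equal orientation, which need no turning, also fell short of 0.1 by Pearson correlation. Over the same probes their Pearson correlations were 0.095 for replicates 1 and 2 and 0.041 for replicates 3 and 4. By Spearman correlation they were 0.039 and 0.230. The mean Pearson correlation over all pairs of arrays was 0.054 as deposited and -0.009 turned over probes, but 0.020 and 0.096 over genes. By Spearman correlation over genes, the 4 pairs of opposite orientation were at 0.12, 0.35, -0.13 and -0.35 as deposited. Ranks over genes thus favour neither direction. The direction used was taken as likely and is not settled. Its basis is that GenePix reports the red over the green channel by default. The ceiling has the same sign in both orientations, with 4 such cells on replicates 1 and 2 together and 7 on replicate 4. It caps high ratios only, the lowest value being -7.61, so it would have this sign with either channel as the numerator. Where the numerator was instead the treated RNA on every array, the values of replicates 3 and 4 have the opposite sign; that reading was run as an alternative.

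The table holds 27648 spots, of which 6472 had a value on at least 1 array. Adjacent odd and even spots carry the same probe, since all 7609 such pairs with a listed gene list the same one, and they were averaged within each array. This gave 3236 probes with a value, 1854 of them on all 4 arrays and 1362 on 3. The platform annotation, an old one, listed 1 gene for 1510 of these probes, several for 13 and none for 1713. Probes without a listed gene are unnamed here and entered only the tests of probes. Gene IDs were matched to the NCBI gene table of the Release 6 plus ISO1 MT assembly; 29 probes had an ID without a match and kept the listed symbol. Probes of the same gene were averaged within each array, which concerned 59 of 1449 genes. The builds of the array's design and of that table were not compared, so no coordinates are given.

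Probes and genes on at least 3 arrays were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment, threshold 0.05). In the gene fit on the deposited scale limma pooled the spread of all genes. The arrays were not centred in this fit, so their offsets enter the SD of every gene. The median SD over genes was 0.46 in this fit and 0.30 with the arrays centred. The pooling is thus no evidence that genes vary alike. All genes measured on 4 arrays therefore share a standard error of 0.27 on the log2 scale and those on 3 arrays one of 0.31. Their own SDs differed, as with 0.03 for Jon25Biii and 1.38 for eIF3a. The p-values of this fit thus do not measure the spread of a single gene over arrays. With the arrays centred, limma lent each gene 9.27 prior degrees of freedom. Dye effects were tested with the dye orientation as a second term, on features measured on all 4 arrays. Of 31 gene lists fixed in advance, the 13 with at least 5 genes on all 4 arrays were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. The genes named in the text follow a rule fixed at the same time: the 12 most changed genes per direction with the same sign on all 4 arrays, those that passed first and the rest by lowest p; from each list the members that passed, up to 4, or else the 2 with the lowest p; and the muscarinic receptor, choline acetyltransferase and acetylcholinesterase genes wherever measured. Only 11 genes with a lower value could be named under the first part, and none of the genes of the last part had a value on at least 3 arrays.

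The fits were tested on simulated data with 200 changed features, averaged over 20 runs. For the 1444 genes 85.2% of 2-fold and 100% of 4-fold changes were recovered, and 3.99% of calls were false. For the 3216 probes these shares were 25.1%, 95.0% and 14.0%. With 200 changes present the adjusted threshold is easier to pass than in the real data, where 3 genes passed. There Cyp28d1, at a log2 ratio of 1.01, did not pass (limma adjusted p = 0.0755). The simulated errors were also independent between features, without any pattern by place on the array. These shares therefore do not give the power or the false share of the real fits. Over 748 genes camera found a list of 30 genes shifted by 0.5 on the log2 scale in 100 of 100 runs and called an unshifted one in 2. The genes of these simulated lists were independent. The tested lists had at most 18 genes on all 4 arrays, with estimated correlations from 0.35 to 0.93. Neither rate therefore carries over to them. The number of arrays limits the precision of every value.

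Alternatives chosen before the data were examined were another presence filter, centring and scaling of the arrays, a dye covariate, the other direction, robust eBayes, array weights, a one-class SAM written for this purpose, other thresholds, 1 probe per gene, and leaving out each replicate in turn. Alternatives added after the data were seen kept the ceiling values, tested each spot alone, centred probes by block and by row, took only probes with 1 listed gene, or turned replicate 1. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the tables.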

Results

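Gene expression in heads of adult Drosophila males was measured after 7 days of feeding on 1.5 mg/ml pilocarpine, an agonist of muscarinic acetylcholine receptors that is widely used to provoke seizures in rodents. The question was which transcripts differ in the head after this chronic treatment. Treated and untreated head RNA of one parallel set were hybridised together on each of 4 arrays, with the dyes exchanged between 2 arrays and the other two. The arrays measured 6257, 4428, 6392 and 5527 spots for replicates 1 to 4. In all 3216 probes and 1444 genes had a value on at least 3 arrays. Values are log2 ratios of pilocarpine over normal food as normalized by the authors, with replicates 3 and 4 turned in sign. This direction was taken from the dye labels and the GenePix default, is not stated by the labels and is not settled. Signs, ranks and tallies hold for this direction. In the other one 52 of the 78 named genes had the opposite sign. The arrays were not centred in the main fit, so the mean of a gene on 3 arrays also depends on which array it lacks. The 480 genes without replicate 2 had a median log2 ratio of 0.20, and of 0.01 with the arrays centred. For the 199 without replicate 4 these were -0.09 and 0.02.

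Pilocarpine feeding was accompanied by higher levels of 3 of the 1444 genes, and none was lower at the same threshold. The transcript of apolpp, which encodes the apolipophorin of the lipoprotein that carries lipids in the haemolymph, rose 2.77-fold, with a log2 ratio of 1.47 ± 0.82 (SD, n = 4; limma adjusted p = 4.32e-05), and was higher on all 4 arrays, at 0.35, 1.46, 1.81 and 2.27. Obp19c, which encodes an odorant-binding protein, rose 3.43-fold to a log2 ratio of 1.78 ± 1.01 (SD, n = 3; limma adjusted p = 2.00e-05) and was higher on each of the 3 arrays that measured it. CG2233, named here after its values were seen because the rule for named genes did not select it, rose 2.40-fold to 1.26 ± 1.05 (SD, n = 3; limma adjusted p = 0.0264) and was higher on each of its 3 arrays. These p-values rest on a standard error pooled over genes and not on the SD beside them. In the fit of single probes the same values of apolpp gave a limma adjusted p of 0.498. The 2 probes of Obp19c disagreed: one had a mean log2 ratio of 3.40 ± 1.92 and the other of 0.16 ± 0.56 (SD, n = 3). With 1 probe per gene, which took the second, Obp19c did not pass. Both apolpp and Obp19c also passed after each array was centred on its median (log2 1.45 and 1.89, limma adjusted p = 0.0274 for each), whereas CG2233 did not (1.07, limma adjusted p = 0.235). The call of apolpp ended without replicate 3 (log2 1.36, limma adjusted p = 0.0999) or replicate 4 (1.21, limma adjusted p = 0.0829), 0 genes passed without replicate 3, 1 without replicate 1, 1 without replicate 4 and 18 without replicate 2, and 0 passed after probes were centred by block and row of the array. In the other direction of replicates 3 and 4, apolpp was at -0.57 and did not pass (limma adjusted p = 0.0725), Obp19c was at 0.04 (limma adjusted p = 0.913) and CG2233 at -1.04, and of the 237 genes that passed, all lower, CG2233 was the 1 shared with the 3 above; with the dye orientation as a covariate 22 passed, 21 higher and 1 lower.

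A further 11 named genes were higher on all 4 arrays without passing the test. Paics, an enzyme of purine synthesis, had a log2 ratio of 0.98 ± 0.62 (SD, n = 4; limma adjusted p = 0.0856) and -0.45 in the other direction. Prps, which makes the phosphoribosyl pyrophosphate that starts the same pathway, had 0.60 ± 0.48 (SD, n = 4). The cytochrome P450 gene Cyp28d1 was at 1.01 ± 1.12 (SD, n = 4; limma adjusted p = 0.0755), with most of it from replicate 4, where it was 2.61; in the other direction it was at -0.60 and passed as lower (limma adjusted p = 0.0464). The fatty acid desaturase gene Desat1 had 0.80 ± 0.67, the immune-induced peptide gene BomT3 0.83 ± 0.67, the inositol oxygenase gene Miox 0.74 ± 0.66 and the RNA helicase gene bel 0.69 ± 0.69 (SD, n = 4 for each). The remaining named genes of this kind were CG11089 at 0.77, Klp59C, a kinesin gene, at 0.56, and CG5958 and CG16898, both at 0.55. With the dye covariate Paics, Cyp28d1, Desat1, BomT3, Miox, bel and CG11089 passed at the same log2 ratios on the deposited scale. With the same covariate and the arrays centred, calls ended for Cyp28d1, BomT3, Desat1, bel and CG11089. Their limma adjusted p was then 0.160, 0.118, 0.0725, 0.0594 and 0.0594. In the other direction these 11 genes lay between -0.60 and -0.21, with bel at -0.59 and Desat1 at -0.42.

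Among genes lower on all 4 arrays none passed. CG4842 was at -0.69 ± 0.52 (SD, n = 4, limma adjusted p = 0.830). It passed with the dye covariate on the deposited scale, but not with that covariate and the arrays centred (limma adjusted p = 0.0594). In the other direction it was at -0.39 (limma adjusted p = 0.152). The long non-coding RNA CR32553 was at -0.54 ± 0.39 and CG17144 at -0.41 ± 0.24 (SD, n = 4 for each). CG7231, CG14015, Tob, CG5550, CG5382, the septate junction gene vari, CG8320 and the mitochondrial glutamyl-tRNA synthetase gene GluRS-m lay between -0.36 and -0.11. For some of them the shared sign rests on array medians below 0. CG14015, CG5550, CG5382 and GluRS-m lay above the median of replicate 1 (-0.14). On replicate 2 (median -0.48) vari, CG8320 and GluRS-m did. These genes are thus not lower on all 4 arrays once the arrays are centred. After each array was centred, 55 of the 748 genes measured on all 4 arrays were higher on all of them (7.35%) and 51 were lower on all (6.82%), where independent signs give 6.25% for each. In the other direction 44 were higher (5.88%) and 70 lower (9.36%) on all.

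**Figure D1:**
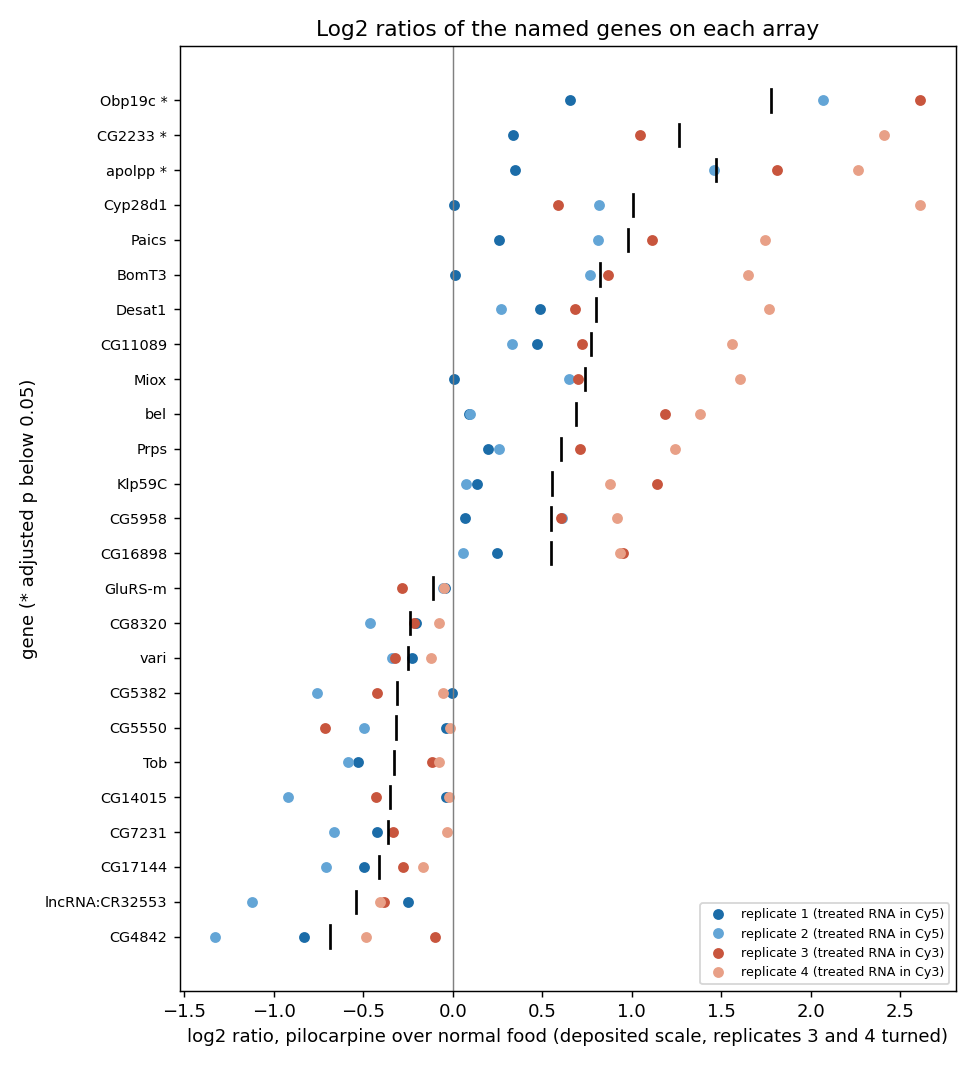
Log2 ratios of pilocarpine over normal food (horizontal axis) of the 3 genes that passed (starred) and of the genes with the same sign on all 4 arrays (vertical axis). Each point is a replicate, coloured by array, and each black bar is the mean over replicates; apolpp ranges from 0.35 on replicate 1 to 2.27 on replicate 4.

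None of the 13 testable gene lists passed the test for a shift as a group (camera, lowest Benjamini-Hochberg adjusted p = 0.239). The power and the rate of false calls for lists of their size and correlation were not estimated. There was 1 list at an unadjusted p under 0.05, and 0 lists with an estimated correlation or with fry. The lowest p belonged to the mitochondrial ribosomal proteins, whose 6 genes on all 4 arrays had a median log2 ratio of 0.16 (camera adjusted p = 0.938 with an estimated correlation). Which list came lowest changed with the setting: in the other direction it was the synaptic vesicle cycle (median -0.54, camera adjusted p = 0.409), with the mitochondrial ribosomal proteins at 0.962, and after centring by block and row it was the muscle markers (camera adjusted p = 0.220). Of the 10 mitochondrial ribosomal protein genes none passed over all genes in the main fit and 1 passed adjusted over the list alone. This was mRpS34, at 0.93 ± 0.96 (SD, n = 4, limma adjusted p = 0.00643 over the list and 0.0283 with the arrays centred), while mRpS11 was at 0.34 ± 0.68 (SD, n = 4). Over all genes mRpS34 passed with the dye covariate and without replicate 2. In the other direction it passed as lower (-0.62, limma adjusted p = 0.0312). Of 14 translation factors 1 passed adjusted over the list alone, the initiation factor gene eIF3a at 0.92 ± 1.38 (SD, n = 3; limma adjusted p = 0.0457 over the list, and 0.535 with the arrays centred, which ends that call), which was 2.51 on replicate 3 and -0.03 on replicate 4. The factor gene eIF4B was at -0.42 ± 0.58 (SD, n = 3). None of 13 cytosolic ribosomal protein genes passed. RpS12 was at 0.33 and RpL28 at 0.30, both without replicate 2, and at 0.14 and 0.11 with the arrays centred.

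Of the 8 measured markers of the head fat body, the tissue that makes lipophorin, apolpp rose and the other 7 did not pass over all genes. Adjusted over the list alone 2 passed, apolpp and Desat1 (limma adjusted p = 0.0124 for Desat1, and 0.00294 with the arrays centred). Besides Desat1 at 0.80, the yolk protein gene Yp2 was at 0.35, the fatty acid synthase gene FASN1 at 0.33, the lipid droplet gene Lsd-2 at 0.32, the storage protein gene Lsp2 at 0.19, sxe2 at 0.10 and Cyp4d21, which the list of cytochrome P450 genes also holds, at -0.10. With the arrays centred these were 0.78, 0.16, 0.14, 0.13, 0.00, -0.09 and -0.12 in the same order, so sxe2 changed sign. Of the 10 odorant-binding and chemosensory genes, Obp19c rose and the other 9 did not pass, their log2 ratios lying between -0.31 and 0.13.

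Genes for detoxification did not pass over all genes. Of 14 cytochrome P450 genes 1 passed adjusted over the list alone, Cyp28d1 (limma adjusted p = 0.00293 over the list, and 0.0528 with the arrays centred, which ends that call), and Cyp4d8 was at 0.66 ± 0.94 (SD, n = 3). None of 6 glutathione transferases passed, with GstD9 at -0.37 and GstE12 at 0.25. None of 5 other genes of xenobiotic metabolism passed, with Gclm, a subunit of glutathione synthesis, at 0.40 and the esterase gene alpha-Est8 at -0.35. Of 5 genes of innate immunity none passed; the antifungal peptide gene Drs was at 0.64 ± 0.70 and the protease gene SPE, which activates the Toll ligand, at 0.58 ± 0.89 (SD, n = 3 for each). The chaperone genes DnaJ-1 and Droj2 were at 0.30 and 0.04. With the arrays centred, the genes of this paragraph on 3 arrays moved. Cyp4d8 was then at 0.47, GstD9 at -0.26, Gclm at 0.21, alpha-Est8 at -0.24, Drs at 0.45 and SPE at 0.39.

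The neuronal lists held no gene that passed over all genes. The one cholinergic gene measured was the nicotinic receptor subunit gene nAChRbeta1, at 0.36 ± 0.57 (SD, n = 3). It lacked replicate 2 and was at 0.17 with the arrays centred. No muscarinic receptor gene had a value on at least 3 arrays. Of 4 neuropeptide genes none passed, with Allatostatin C (AstC) at -0.41 ± 0.40 and the clock neuropeptide gene Pdf at -0.37 ± 0.40 (SD, n = 4 for each). With the arrays centred AstC passed adjusted over the list alone (log2 -0.43, limma adjusted p = 0.0439). The clock gene per was at 0.44 ± 0.23 (SD, n = 3), and at 0.25 with the arrays centred. Of 7 genes of the synaptic vesicle cycle AP-2sigma was at 0.44 and alphaSnap at 0.39, each on 3 arrays. The camera test of this list used only its 5 genes on all 4 arrays, without AP-2sigma and alphaSnap, and gave an adjusted p = 0.444. Of 11 other transmitter genes the receptor genes DopEcR and 5-HT2A were at 0.45 and -0.52. Of 9 genes of Gq and calcium signalling, the pathway below muscarinic receptors, Nckx30C was at 0.46 and CanB at -0.36. Ion channel and pump genes stj and nrv3 were at 0.39 and 0.22. The memory genes orb2 and stau were at 0.36 and -0.28, and the phototransduction genes Arr1 and santa-maria at 0.26 and -0.21. Other genes of this paragraph on 3 arrays also moved once the arrays were centred. AP-2sigma was then at 0.55, alphaSnap at 0.20, 5-HT2A at -0.41, stj at 0.20, nrv3 at 0.14 and santa-maria at -0.10.

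Energy metabolism and structural genes also held none that passed over all genes. Of 23 genes of oxidative phosphorylation the complex I subunit gene ND-13B was at -0.62 ± 0.52 (SD, n = 4) and Cyt-c1 at 0.31, and in the other direction they were at -0.29 and -0.51; the median of the 18 on all 4 arrays was 0.00. Hexokinase C (Hex-C) and Tpi of glycolysis were at 0.48 and 0.26, and Mdh1 and Idh3a of the tricarboxylic acid cycle at 0.35 and -0.22. Of 8 muscle genes the myosin light chain gene Mlc1 was at -0.52 ± 0.31 (SD, n = 3) and Act79B at 0.28. The proteasome genes Rpt3 and Prosbeta3 were at 0.40 and 0.35. The genes of starvation and insulin signalling sug and foxo were at 0.33 and 0.22. The cuticle genes Cpr76Bd and TwdlE were at -0.30 and 0.21, and the cytoskeletal genes cib and betaTub60D at 0.29 and -0.27. Among markers of other cells and body parts, the glial genes Gs2 and Nrg were at 0.11 and -0.05, the haemocyte gene Col4a1 at 0.20, the testis gene ocn, the only one measured of its list, at 0.41 (limma adjusted p over the list = 0.193, and 0.0419 with the arrays centred) and the digestive genes Jon25Biii and Mal-A2 at 0.29 and -0.24. Genes of this paragraph on 3 arrays moved once the arrays were centred. Hex-C was then at 0.29, Tpi at 0.07, Cyt-c1 at 0.12, Mlc1 at -0.41, Act79B at 0.09, Rpt3 at 0.21 and Prosbeta3 at 0.16. In the same setting sug was at 0.44, Cpr76Bd at -0.49, cib at 0.10, betaTub60D at -0.16, Col4a1 at 0.13, ocn at 0.52 and Jon25Biii at 0.10.

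At the level of single probes, with or without a listed gene, 0 of 3216 passed (limma, lowest adjusted p = 0.238). An unadjusted p under 0.05 was found for 121, and 1 passed with the one-class SAM. The probe of apolpp was at the same 1.47 ± 0.82 (SD, n = 4) with a limma adjusted p = 0.498, and the Obp19c probe with the higher ratio at 3.40 with 0.238. Probes without a listed gene spread more widely than listed ones: on replicates 1 to 4 the SD over probes was 0.70, 1.07, 0.90 and 0.80 without and 0.28, 0.44, 0.47 and 0.41 with a listed gene. Duplicate spots of unlisted probes correlated less, with r between 0.34 and 0.66 against 0.77 to 0.88 for listed probes, across probes, which are not independent replicates. The count rose to 12 without replicate 1 and 13 without replicate 3, to 3 with robust eBayes and to 4 when only the probes with 1 listed gene were tested.

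Dye orientation shifted no probe past the threshold (0 of 1854; limma, lowest adjusted p = 0.0679; 430 at an unadjusted p under 0.05). At the gene level 125 of 748 genes differed by dye on the deposited scale in the direction used here, all lower in Cy5, and 0 did once the arrays were centred. The dye coefficient is the mean of the deposited ratios, which is also the pilocarpine effect in the other direction. In that direction the 125 would be lower with pilocarpine, so the dye is not told apart from the treatment here. The median dye coefficient over the 748 genes was -0.32 before centring and 0.01 after it. For apolpp the dye coefficient was -0.24 with the arrays centred (limma adjusted p = 0.792).

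The arrays shared little across genes. Over the 6 pairs of arrays the mean Pearson correlation was -0.009 over all probes (SD over pairs 0.096) and 0.096 over genes (SD over pairs 0.27), after replicates 3 and 4 were turned. Over genes, replicates 2, 3 and 4 correlated with each other (r = 0.19, 0.40 and 0.40), whereas replicate 1 correlated with them at -0.05, -0.12 and -0.24. In the other direction replicate 2 stood apart instead, at -0.05, -0.19 and -0.40 with replicates 1, 3 and 4, and replicate 1 was at 0.12 and 0.24 with replicates 3 and 4. The pairs of equal dye orientation do not depend on the direction: r was -0.05 for replicates 1 and 2 and 0.40 for replicates 3 and 4.

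**Figure D2:**
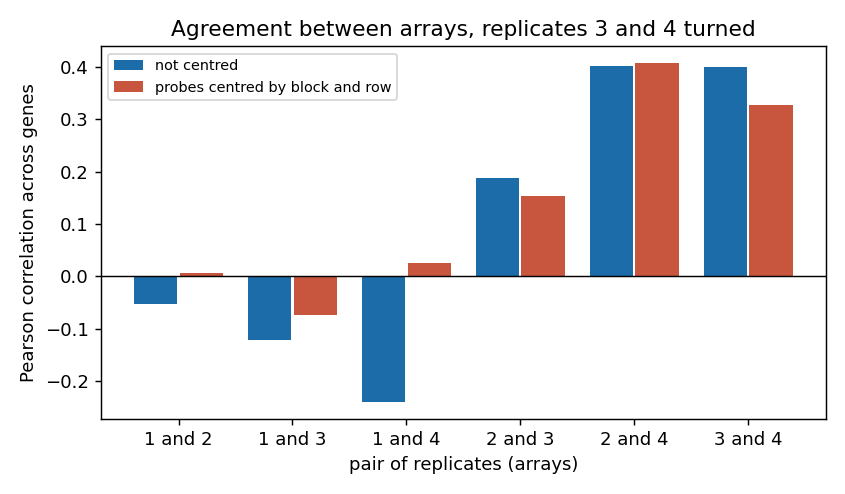
Pearson correlation across genes (vertical axis) for each pair of arrays (horizontal axis), with replicates 3 and 4 turned. Blue bars use values that were not centred and red bars values after probes were centred by block and row. Among the blue bars the 3 pairs with replicate 1 lie below 0 and the other three lie between 0.19 and 0.40; without the turn, the pairs of opposite dye orientation have the opposite sign.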

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

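The tests of apolpp, the test of place on the array for replicate 1 and the counts over sign patterns were chosen or written down after the results were seen; the test of the orientation of replicate 1 was written down before. Chance puts 1 in 20 groups of 4 values past the limit used for a value far from the others, and 4 of 51 groups were past it, where chance gives about 2.5.

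ND-13B, a subunit of respiratory complex I, was at 0.16 on replicate 3 and at -0.95, -0.86 and -0.82 on the others. Arr1, the arrestin of photoreceptors, was at 1.00 on replicate 4 and between -0.01 and 0.08 on the others. GluRS-m was at -0.29 on replicate 3 and between -0.06 and -0.04 elsewhere. The correlation between neighbouring spots of different probes was 0.449 on replicate 3 and 0.170, 0.183 and 0.217 on replicates 1, 2 and 4.

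The higher level of apolpp was weighed first. A dye bias of this gene is argued against only in the direction used here. With a dye term its adjusted p was 1.37e-10 in limma as deposited, the lowest over its alternatives, which reached 0.184. With the arrays centred it was 0.0239, and the dye coefficient was -0.24 against a pilocarpine coefficient of 1.45. The dyes are balanced over the arrays, so a dye term changes the error and not the mean. In the other direction apolpp was at -0.57 and the 1.47 would be the difference between dyes, so a dye bias stays open there. A larger share of fat body RNA in the treated pools would raise the other fat body markers about as much, but the median centred log2 ratio of the other 7 was 0.13 (SD over genes 0.30) against 1.45 for apolpp, and as deposited it was 0.32 (SD over genes 0.28) against 1.47. The 7 ranged from 0.78 for Desat1 to -0.12 for Cyp4d21 with the arrays centred. Their median does not exclude a smaller rise in the share of fat body RNA. Place on the array stays open: centring by block and row moved apolpp from 1.47 ± 0.82 to 1.24 ± 0.54 (SD, n = 4) and its standard error from 0.27 to 0.19, and the call ended (limma adjusted p = 0.184, from 4.32e-05 as deposited and 0.0274 with the arrays centred) although the ratio of apolpp to its standard error was 5.43 as deposited, 6.64 with the arrays centred and 6.53 after centring by block and row, since limma pooled the spread of all genes in the first fit and lent each gene 9.27 prior degrees of freedom in the second and 5.66 in the third. A response of the apolpp gene itself to pilocarpine may account for the change and remains an untested hypothesis, and the probe next to it on the array, which has no listed gene, had a mean of 1.63 ± 1.18 (SD, n = 4), while of the other probes in its row one was at 0.16 ± 0.65 (SD, n = 3), one at -0.25 (n = 2) and one at 1.45 ± 3.43 (SD, n = 4).

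Replicate 1 running against the other arrays was weighed next, a pattern of the direction used here, since in the other direction replicate 2 runs against the rest (r = -0.05, -0.19 and -0.40 with replicates 1, 3 and 4). By Pearson correlation, place on the array may account for the negative part of this. The mean correlation of replicate 1 with the others across genes was -0.14 and became -0.014 after centring by block and row. That among replicates 2, 3 and 4 went from 0.33 to 0.30. By Spearman correlation replicate 1 was at -0.09, -0.12 and -0.35 with replicates 2, 3 and 4. After that centring these were still below 0, at -0.06, -0.10 and -0.09. By rank a negative part thus remains, and the lack of a positive correlation stays unexplained. A mislabelled orientation of replicate 1 stays open: of 60 genes that replicates 2, 3 and 4 placed on the same side by at least 0.5 on average, 25 had that sign on replicate 1 (41.7%, exact 95% binomial interval over genes 29.1 to 55.1%), and 22 of 40 did after centring by block and row. With the arrays centred, turning replicate 1 gave 239 genes at an unadjusted p under 0.05 against 107 as labelled, and 0 against 2 after adjustment; the same signs arise in the other direction by turning replicate 2. A pool of flies that responded less was not tested.

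The 4 arrays have 8 sign patterns, too few for a share under 0.05. The labelled pattern gave 3 genes, and 3 of the 8 patterns gave as many, with 237 in the highest other one, which turns no array. That count, many times the labelled one, points to a structure shared by all 4 arrays as deposited, their medians below 0. With the arrays centred the labelled pattern gave 2 genes and the highest other pattern 0, so that 1 of 8 gave as many. At an unadjusted p under 0.05 the order differed, with 107 genes for the labelled pattern, 239 for the one with replicate 1 turned and 126 for the one that turns no array. For probes the labelled pattern and the highest other gave 0, as for gene lists, so that 8 of 8 gave as many in both cases.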

How the results depend on the processing

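Centring by block and row, turning replicate 1 and testing only listed probes were chosen after the data were seen. From 0 as the main count, probes that passed came to 3 with robust eBayes, 1 with the one-class SAM, 4 among probes with 1 listed gene, and 0 to 13 when each replicate was left out. From 3, genes came to 1 when measured on all 4 arrays, 22 with the dye covariate, 237 in the other direction, 5 at an adjusted p below 0.1, 0 after centring by block and row, 5 with replicate 1 turned, and 0 to 18 when each replicate was left out. The 237 come from array medians below 0 that then add up, since with the arrays centred that reading gave 0; of the 3 genes Obp19c and CG2233 were not measured on all 4 arrays; the cause of the others was not tested. In the other direction, log2 ratios that had passed or then passed changed sign: apolpp -0.57, CG2233 -1.04, Cyp28d1 -0.60, bel -0.59, Nckx30C -0.64, orb2 -0.56, Cyp4d8 -0.94, foxo -0.64, Col4a1 -0.74, Drs -0.73, SPE -0.84, nrv3 -0.69, mRpS34 -0.62, mRpS11 -0.56, DopEcR -0.76, Gclm -0.63, Rpt3 -0.83 and eIF3a -0.73. Over 78 named genes and 1034 gene settings, 19 values came past the threshold, 11 fell short of it and these 18 changed sign with a call on either side. Of the rest, 932 kept their call or, uncalled, moved by less than 1 SD over arrays, and 54 uncalled values moved by more. Called or not, 73 values changed sign, 52 of them in the other direction. Gene lists (0) and probes with a dye effect (0) kept their counts in every setting run, and the mean correlation between arrays was -0.0045 over probes on all 4 arrays against -0.0089. The authors' spot filters limit what was measured, and which of them removed a spot was not tested: 480 genes lacked replicate 2, and their median log2 ratio was 0.20 as deposited and 0.01 with the arrays centred. The test against 0 is itself paired, because each array holds the ratio within 1 pair.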

Other observations

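These values were looked at after the results were seen. The placement of spots left a trace in the values. Row within a block accounted for 20.9, 8.34, 16.5 and 26.2% of the variance over listed probes on replicates 1 to 4, and block for 18.7, 6.08, 19.4 and 8.83%. The 199 genes missing on replicate 4 had a median log2 ratio of -0.09 as deposited and 0.02 with the arrays centred, and the 17 missing on replicate 1 had 0.03 and -0.04.

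Probes without a listed gene held the 3 lowest p-values of the probe test. The top one had a mean log2 ratio of 2.96 ± 1.28 and the next one -2.54 ± 1.07 (SD, n = 3 for each), both with a limma adjusted p of 0.238; their genes are unnamed here.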
